A study of Drosophila melanogaster with 6 samples.

How the data were processed

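Total RNA of Drosophila melanogaster embryos was measured on 6 Affymetrix expression arrays, 3 for embryos of flies raised on control food with the solvent DMSO and 3 for embryos whose parents were fed methylmercury (MeHg). The group and replicate number of each array came from its title. The titles and source names call the DMSO samples late embryonic tissue and the MeHg samples whole animal, both with the words whole brain, while the descriptions call both groups embryos, so the tissue and the age of the embryos are not settled by the labels. Per the labels, labelling followed the standard Affymetrix protocol and the extraction protocol was not supplied. The software that turned the scans into probe set values, its version and its scaling step are not given in the sources used here.

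The deposited values are intensities, 1 per probe set and array, on a linear scale and all above 0. The mean after trimming 2% of the values at each end was 2500 on each of the 6 arrays, so each array had been scaled to 1 level by the authors, while the medians ran from 330 to 432 and the arrays had not been brought to 1 distribution. This scaling was kept. A total shift of all transcripts between groups would be removed by such scaling, and a change in a few very abundant transcripts would move the rest slightly.

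The table held 18769 probe sets after 183 control probe sets were left out. Gene names came from the platform annotation, with symbols looked up through the gene identifier in the RefSeq gene table of Release 6 (no symbol changed, and 103 probe sets whose identifier was not matched kept the name of the annotation). Exactly 1 symbol was given for 13647 probe sets, several for 402 and none for 4720. No gene was named from a probe set with several symbols. For the 1094 of 11982 genes with several probe sets, the brightest over the 6 arrays stood for the gene, and the mean of all of them was an alternative.

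A background limit was set on each array as the 95th percentile of 44 control probe sets for bacterial and artificial transcripts. It ran from 125 to 198, and between 59.3% and 66.1% of probe sets lay above it. A probe set not above the limit on any array of a group has only a bound there. The fold is then given as at least the mean log2 level of the brighter group over, per array, the higher of the limit and the measured value, and no fold is given where this is under 1 or both groups are below the limit. Only 6 arrays were measured, and that number limits the precision.

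Values were tested as log2(value + 16) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group as the only term), with Benjamini-Hochberg adjustment over all 18769 probe sets and a threshold of 0.05. Fold changes are on the log2(value + 16) scale, which understates the change of dim probe sets. Gene lists were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 of 34 lists with at least 5 measured genes. The test was run again with a correlation estimated per list and with fry, which asks whether a list's own genes move one way and does not set them against other genes. The lists, the test, the main alternatives and the naming rule were fixed before the data were examined.

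The rule named, in each direction, the 12 probe sets with the largest change among those past the threshold without overlap between groups. Places left over went to the smallest unadjusted p among probe sets that differed by at least 1.5-fold. Within each list it named up to 4 members past the threshold, or otherwise the 2 with the smallest unadjusted p. All measured Enhancer of split and Turandot genes could be named as well. Genes named outside this rule are said to be so where they appear.

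The titles give both groups the replicate numbers 1, 2 and 3. Deviations from the group means correlated across probe sets within each number, at 0.61 for replicate 1, 0.30 for replicate 2 and 0.23 for replicate 3. Crosswise the values were similar, at 0.33 for DMSO 3 with MeHg 2 and 0.17 for DMSO 2 with MeHg 3. Deviations cancel within a group, so a shared difference of replicate 1 by itself makes the other arrays correlate. The values therefore set apart replicate 1 only, and pairs 2 and 3 follow the titles alone. The numbers were taken to pair the arrays, although nothing in the labels says that a number marks a shared day or batch. A fit with the replicate number as a block was computed for every result. The other alternatives were quantile normalization, median centring, a pseudocount of 1 or 64, leaving out the dimmest 25% or 50% of probe sets, a variance trend with robust settings, array weights, a threshold of 0.1, a minimum log2 change of 1, 1 probe set per gene, and leaving out each array in turn. Leaving out both replicate 1 arrays, the block together with the variance trend, and the block together with the estimated correlation were chosen after seeing the data.

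The fits were tested on simulated data with the real mean and residual spread of each probe set and independent noise, in which 200 of the 18769 probe sets, all brighter than the median, were changed. Without the block, none of the 2-fold and 4-fold changes and 79.0% of the 16-fold changes were recovered. With the block, none of the 2-fold and 4-fold changes and 87.0% of the 16-fold changes were recovered. With a variance trend and robust settings, 29.0% of the 4-fold changes were recovered without the block and 66.0% with it. In a simulated list test over 11982 genes, a list shifted by 1 on the log2 scale was called and 0 of the other lists were. Its noise was independent between genes, unlike the measured lists (estimated correlation 0.87 for DNA replication genes). Its shift was also larger than the mean differences of the lists called below (0.31 to 0.52). The simulation therefore cannot show how often lists are called falsely in the measured data.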

Results

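Expression was measured on 6 arrays of Drosophila embryos, 3 from flies kept on food with DMSO, the solvent control, and 3 from flies fed methylmercury, an organic mercury compound that is toxic to the developing nervous system. The comparison asks which transcripts differ in embryos after feeding of the parents. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The ratio of 3-prime to 5-prime signal of an actin control transcript, a measure of RNA integrity, was 2.32, 1.62 and 2.27 on DMSO arrays 1, 2 and 3, and 3.15, 1.51 and 2.05 on MeHg arrays 1, 2 and 3.

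The probe sets that differed most clearly between groups belonged to dim genes with varied functions. Higher in the MeHg embryos were the noncoding RNA lncRNA:iab8 of the bithorax region (signal 199 ± 39.8 against 27.7 ± 12.7, SD, n = 3 each, at least 1.27-fold), the receptor tyrosine phosphatase Ptp99A (172 ± 28.5 against 23.3 ± 5.03, at least 1.11-fold) and the mucin Muc68D (101 ± 17.2 against 6.77 ± 2.13, below the background limit in both groups). Lower were the ionotropic receptor Ir76a (43.0 ± 20.8 against 292 ± 43.3, at least 1.77-fold), CG31823 (52.6 ± 24.1 against 295 ± 48.4, at least 1.79-fold), the odorant-binding protein Obp46a (75.4 ± 23.3 against 250 ± 23.0, at least 1.53-fold) and the nuclear receptor Hr38 (36.7 ± 15.0 against 187 ± 36.4, at least 1.17-fold). None of these genes passed the threshold. Of 183 control probe sets, 16 also had all MeHg arrays above all DMSO arrays, and 4 the reverse. Some rose from levels like those of the named genes, such as means of 25.6 in DMSO and 169 in MeHg, or 6.60 and 83.3. Whether the dim probe sets above measured their fly genes or background was not tested.

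The other genes named by the rule on the higher side were CG13171, tbrd-2, CG42233, CG43448, the serine protease Ser7, the odorant receptor Or35a, CG34040, lncRNA:CR43830 and CG18586. On the lower side they were CG2983, the homeobox gene Hmx, Uch-L5R, CG30222, rg, the cytochrome P450 gene Cyp6t3, CG30412 and CG32459. For all 24 the groups did not overlap, which fixes the same direction in 3 of 3 pairs, and their limma p-values after Benjamini-Hochberg adjustment ran from 0.607 to 0.996. Of the 24, 8 were not above the background limit on any array, 16 were not above it on any array of 1 group, and 0 were above it on all 6 arrays.

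Over all 18769 probe sets, limma found 0 higher and 0 lower in MeHg after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.607. At an unadjusted p under 0.05 there were 511 (308 higher, 203 lower), against 938 that chance alone would give. With the replicate number as a block the counts were again 0 and 0, with 945 at an unadjusted p under 0.05 (571 higher, 374 lower). The groups did not overlap at 994 probe sets, or 5.30% (2.57% of the 10194 brighter probe sets). Chance gives 10% for exchangeable arrays, and the 3 other splits that part all numbered pairs gave 4.65%, 5.19% and 5.23% (1.25%, 2.09% and 2.50% of the brighter probe sets). A variance trend with robust settings gave 0 with 331 at an unadjusted p under 0.05, array weights gave 0 with 2634, and block and trend together, chosen after seeing the data, gave 0 with 827. In simulated data the default fit without the block recovered none of the 4-fold and 79.0% of the 16-fold changes, and the fit with block, variance trend and robust settings recovered 66.0% and 88.0%.

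Genes of DNA replication and the cell cycle were the list with the smallest adjusted p. All 18 measured members of 30 were higher in MeHg, by a mean log2 difference of 0.34 (0.26, 0.47 and 0.27 in pairs 1, 2 and 3). The examples with the smallest p were Cdc6, a loader of the replicative helicase (3007 ± 873 against 1917 ± 322, SD, n = 3 each, log2 difference 0.62 ± 0.34 SE), and Orc5, a subunit of the origin recognition complex (1208 ± 291 against 793 ± 328, 0.67 ± 0.43). The list rose against all other genes in limma's camera (adjusted p = 0.00543, Benjamini-Hochberg over 32 lists). With the replicate block the list also passed (adjusted p = 3.26e-06 by the same test). It passed as well without both replicate 1 arrays and with block and variance trend, both chosen after seeing the data. With an estimated correlation the call was lost (adjusted p = 0.971, unadjusted p = 0.364, estimated correlation 0.87), and with block and estimated correlation likewise (adjusted p = 0.878, unadjusted p = 0.0581, estimated correlation 0.07). No member passed the threshold over all genes, and 0 passed when adjusted over the list alone by limma, where 0 also had an unadjusted p under 0.05 (2 with the block). The call was also lost without DMSO 1 (adjusted p = 0.822), without MeHg 2 (0.783) and without MeHg 3 (0.0582), and with array weights (0.103), by camera with Benjamini-Hochberg adjustment. Leaving out DMSO 1, MeHg 2 or MeHg 3 gives replicate 1 more weight in MeHg than in DMSO. In replicate 1 of both groups the list was lower, by a median log2 difference of -0.98. The losses without these arrays can therefore come from the replicate number alone.

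Proneural genes, which commit cells to the neural fate, and Bearded family genes were higher in MeHg as a list. Of 11 measured members 10 were higher, by a mean log2 difference of 0.52. BobA, a Bearded family member, had 5115 ± 2745 against 2277 ± 778 (SD, n = 3 each, log2 difference 1.10 ± 0.49 SE), and Brd, the family's founding gene, had 3385 ± 805 against 2013 ± 736 (0.79 ± 0.39). Camera gave an adjusted p of 0.0101 (Benjamini-Hochberg), which became an adjusted p of 0.971 with an estimated correlation. The mean difference was 1.42 in pair 1, 0.12 in pair 2 and 0.02 in pair 3. The 3-prime to 5-prime ratios of 3 control transcripts were also higher in MeHg in pair 1 (mean log2 difference 0.39) and lower in pairs 2 and 3 (-0.19 and -0.13). The call was lost without DMSO 1 (adjusted p = 0.728), MeHg 1 (0.117) or MeHg 2 (0.230), and with array weights (0.712), by camera with Benjamini-Hochberg adjustment. In replicate 1 of both groups the list was lower, by a median log2 difference of -0.82. Leaving out DMSO 1 or MeHg 2 gives replicate 1 more weight in MeHg, so these losses can come from the replicate number. By limma 0 members passed the threshold over all genes, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05.

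Digestive enzyme genes of the gut were the remaining list past the threshold, with 18 of 25 measured members higher and a mean log2 difference of 0.31. Jon65Ai, a serine protease, had 103 ± 76.0 against 18.4 ± 9.91 (SD, n = 3 each), below the background limit in both groups, and Jon66Ci of the same family had 211 ± 97.8 against 347 ± 103 (log2 difference -0.74 ± 0.44 SE). Camera gave an adjusted p of 0.0463 (Benjamini-Hochberg), which became an adjusted p of 0.971 with an estimated correlation. The mean difference was 1.12, -0.37 and 0.18 in pairs 1, 2 and 3, so that it too was largest in pair 1, where the 3-prime to 5-prime ratios were higher in MeHg (0.39). The call was lost without DMSO 1 (adjusted p = 0.538), DMSO 2 (0.123), MeHg 1 (0.698) or MeHg 3 (0.478), with array weights (0.0736) and with a pseudocount of 1 (0.0519), by camera with Benjamini-Hochberg adjustment. By limma 0 members passed the threshold over all genes, 0 when adjusted over the list alone and 1 at an unadjusted p under 0.05.

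**Figure D1:**
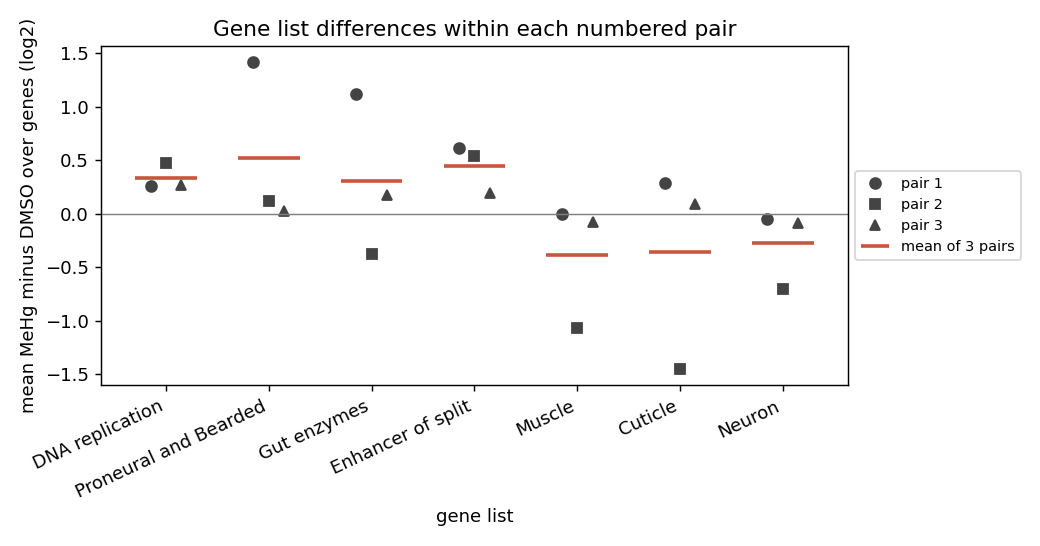
Mean log2 difference, MeHg minus DMSO, over the measured genes of 7 lists (y axis) for each numbered pair of arrays (points) and over the 3 pairs (bars). DNA replication genes lie between 0.26 and 0.47 in the pairs, while the muscle, cuticle and neuron lists are lowest in pair 2 at -1.07, -1.45 and -0.70.

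Enhancer of split genes, the direct transcriptional targets of Notch signalling, were higher in MeHg at 8 of 9 measured members, by a mean log2 difference of 0.45 (0.62, 0.54 and 0.19 in pairs 1, 2 and 3). E(spl)m5-HLH had 2225 ± 983 against 1465 ± 1023 (SD, n = 3 each, log2 difference 0.87 ± 0.76 SE). E(spl)m4-BFM had 3612 ± 1614 against 2215 ± 1391 (0.86 ± 0.70), E(spl)malpha-BFM differed by 0.86 ± 1.42 and E(spl)mdelta-HLH by 0.66 ± 0.87. E(spl)mbeta-HLH, E(spl)m7-HLH, E(spl)m2-BFM and E(spl)m3-HLH differed by 0.43, 0.33, 0.26 and 0.08, and E(spl)m6-BFM by -0.31. The list did not pass the threshold by camera with Benjamini-Hochberg adjustment (adjusted p = 0.182). With the replicate block it did (adjusted p = 0.00097), and with block and estimated correlation it did not (adjusted p = 0.878). It also passed without the dimmest 50% of probe sets (0.0198), and without DMSO 2 (0.0113), DMSO 3 (0.031) or MeHg 1 (0.00483). Leaving out any of these arrays gives replicate 1 more weight in DMSO than in MeHg. In replicate 1 of both groups the list was lower, by a median log2 difference of -2.23. The passes without these arrays can therefore come from the replicate number alone. With the settings chosen after seeing the data the list passed without both replicate 1 arrays (0.00913) and with block and variance trend (4.32e-06). By limma 0 members passed over all genes, 0 when adjusted over the list alone, and 0 (3 with the block) had an unadjusted p under 0.05. Notch pathway components, 12 of 16 higher, were not called (adjusted p = 0.548 by camera with Benjamini-Hochberg adjustment). Among them were bib, a neurogenic channel gene, at a log2 difference of 0.67 ± 0.45, and mam, a coactivator of Notch, at -0.25 ± 0.30.

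Muscle, cuticle and neuron genes were mostly lower in MeHg. Muscle markers were lower at 17 of 18 measured genes (mean log2 difference -0.38, adjusted p = 0.052 by camera with Benjamini-Hochberg adjustment), cuticle and epidermis genes at 40 of 48 (-0.36, 0.177) and neuron markers at 21 of 23 (-0.28, 0.239). Mlp60A, a muscle LIM protein, had 57004 ± 37833 against 69611 ± 23661 (SD, n = 3 each), the cuticle genes Cpr11A and Cpr12A differed by 1.02 ± 0.83 and -0.32 ± 0.28 (log2, SE), and Nrx-1, a synaptic adhesion gene, by -0.82 ± 0.72. The muscle list passed the threshold with quantile normalization (adjusted p = 0.0387 by the same test), median centring (0.0211) and a pseudocount of 64 (0.0352). It also passed without the dimmest 25% (0.0326) or 50% (0.0297) of probe sets, with a variance trend (0.0315) and with the mean of a gene's probe sets (0.0375). It did not pass with a pseudocount of 1 (0.0649), array weights (0.338), an estimated correlation (0.971) or fry (0.962). Nor did it pass without DMSO 1 (0.958), MeHg 2 (0.783) or MeHg 3 (0.293), and camera placed it higher in MeHg without DMSO 1 or MeHg 2. With the replicate block these lists passed the threshold, at adjusted p-values of 0.00679, 0.00973 and 0.00823 by camera with Benjamini-Hochberg adjustment, each of which became 0.878 with an estimated correlation. Without MeHg 1 they also passed (1.48e-05, 1.16e-06 and 0.000533 by the same test). So did muscle and neuron markers without DMSO 2 (0.00702 and 0.0214) and all of these lists without DMSO 3 (0.00669, 0.00502 and 0.031). Each of these fits gives replicate 1, where the medians of these lists were higher in both groups, more weight in DMSO than in MeHg. Cuticle genes passed without the dimmest 50% of probe sets (0.0327). The muscle, cuticle and neuron lists also passed without both replicate 1 arrays (0.00129, 6.08e-05 and 0.0268) and with block and variance trend (0.000392, 0.000654 and 0.00476), both chosen after seeing the data. The differences lay mainly in pair 2, at -1.07 for muscle, -1.45 for cuticle and -0.70 for neurons, against -0.00, 0.29 and -0.05 in pair 1 and -0.08, 0.09 and -0.09 in pair 3. Respiratory chain genes of the mitochondria were lower at 30 of 33 (mean -0.09), segmentation genes higher at 14 of 18 (0.27) and nucleolar genes higher at 11 of 13 (0.11). Their adjusted p-values by camera with Benjamini-Hochberg adjustment were 0.239, 0.182 and 0.497 without the block, 0.0272, 0.0312 and 0.0496 with it, and 0.878 for each with block and estimated correlation. By the same test the respiratory chain list also passed without DMSO 2 (0.00514), DMSO 3 (0.0301) or MeHg 1 (0.0015), segmentation genes without DMSO 2 (0.0214) or DMSO 3 (0.00674), and nucleolar genes without MeHg 1 (0.0113). Segmentation genes passed without the dimmest 50% of probe sets (0.0417). With block and variance trend the respiratory chain, segmentation and nucleolar lists had 0.000245, 0.00589 and 0.00221.

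Several of these lists also differed between replicate numbers, which was not tested per list. In the replicate 1 arrays of both groups, Enhancer of split genes were lower than in replicates 2 and 3 by a median log2 difference of -2.23, neuroblast markers by -1.23, DNA replication genes by -0.98 and segmentation genes by -0.96. Cuticle genes were higher there by 1.73, muscle markers by 1.61, neuron markers by 1.23 and respiratory chain genes by 0.48. Leaving out DMSO 2, DMSO 3 or MeHg 1 gives replicate 1 more weight in DMSO than in MeHg, which by itself moves such lists. List calls made after leaving out any of these arrays, above and below, are therefore no separate support for a group difference. Leaving out DMSO 1, MeHg 2 or MeHg 3 gives replicate 1 more weight in MeHg instead. For such lists, calls lost without 1 of those arrays are therefore no separate evidence against a group difference. The first principal component, with 81.5% of the variance over the 10194 brighter probe sets, placed DMSO 1 at -81.2 and MeHg 1 at -78.8, the other DMSO arrays at 21.7 and 32.9, and MeHg 2 and 3 at 72.8 and 32.5. For the replicate number, limma with a variance trend and Benjamini-Hochberg adjustment called 4851 of 18769 probe sets. The default limma fit called 0, with 5380 at an unadjusted p under 0.05. By the first of these fits, all 9 Enhancer of split genes passed, all lower in replicate 1. So did 13 of 18 DNA replication genes, all lower, and 28 of 33 respiratory chain genes, all higher. Of 48 cuticle genes 12 passed (11 higher), and of 18 muscle markers 8 passed (6 higher, 2 lower).

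**Figure D2:**
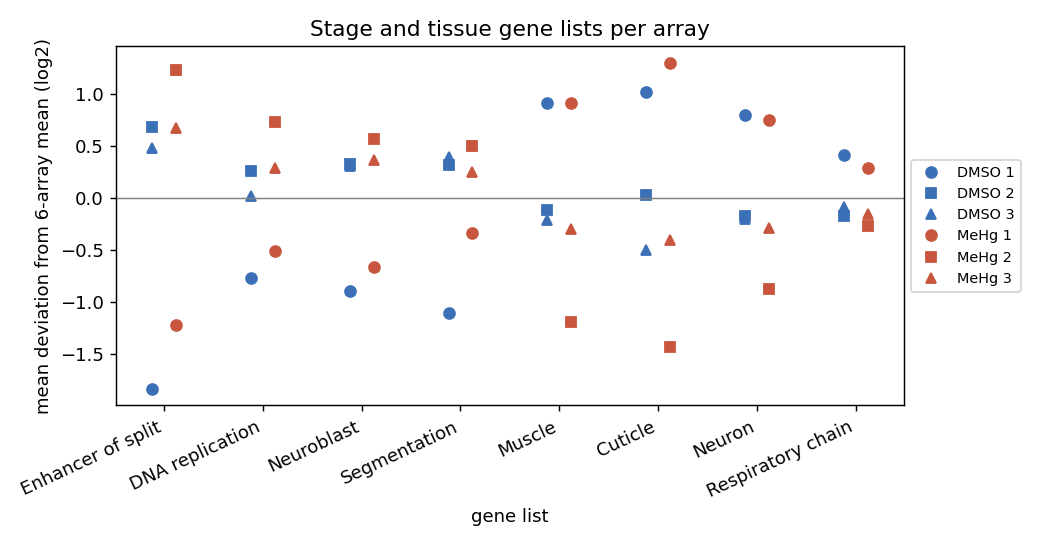
Mean log2 deviation from the 6-array mean (y axis) of 8 stage and tissue gene lists on each array, with DMSO in blue, MeHg in red and 1 symbol shape per replicate number. The replicate 1 arrays of both groups lie apart from the others in each list (for muscle, 0.91 on DMSO 1 and 0.91 on MeHg 1), and MeHg 2 lies at the opposite end (-1.19 for muscle).

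Thiol redox, metal response, heat shock and cytochrome P450 genes had differences of both signs, and no member passed the threshold. Among 38 glutathione S-transferase and thiol redox genes 15 were higher and 23 lower, among 14 metal response genes 8 and 6, among 12 heat shock and chaperone genes 7 and 5, and among 55 cytochrome P450 genes 26 and 29. Adjusted p-values by camera with Benjamini-Hochberg adjustment were 0.897, 0.564, 0.899 and 0.897 for these lists, and the P450 list passed the threshold, lower in MeHg, without MeHg 1 (0.00985). The P450 list had an adjusted p = 0.971 with an estimated correlation on all 6 arrays, and 0.878 with the block as well. Gclm, the modifier subunit of the enzyme that limits glutathione synthesis, had 942 ± 140 against 630 ± 116 (SD, n = 3 each, log2 difference 0.57 ± 0.29 SE), and GstD8 had 475 ± 87.6 against 331.5 ± 118. The metallothioneins MtnB and MtnC were below the background limit in both groups (16.8 ± 4.02 against 38.4 ± 15.9 for MtnB, 16.8 ± 7.84 against 70.6 ± 43.0 for MtnC). The mean and median differed in sign for the metal list (-0.15 and 0.05) and the heat shock list (-0.04 and 0.03), and camera took the direction of the mean in both. Hsp68, a heat-inducible chaperone, differed by 1.21 ± 1.29 (log2, SE), and the chaperone gene Hsc70-2 had 48.6 ± 30.6 against 178 ± 91.5 (at least 1.03-fold lower). The bound of Hsc70-2 was 0.82 without DMSO 2 and 1.38 without DMSO 3, so it does not hold under each choice of arrays. The P450 gene Cyp316a1 had 15.7 ± 4.06 against 95.8 ± 57.4, below the limit in both groups.

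The antifungal peptide gene Drs had a signal of 598 ± 134 in MeHg against 186 ± 56.8 in DMSO (SD, n = 3 each), a log2 difference of 1.62 ± 0.35 (SE) without overlap between the groups. Its adjusted p by limma with Benjamini-Hochberg adjustment was 0.996. Its list of antimicrobial and immune genes had 9 of 20 members higher and was not called (adjusted p = 0.947 by camera with Benjamini-Hochberg adjustment), and AttD in the same list was below the background limit in both groups. The 5 measured Turandot genes, which encode stress-induced secreted peptides, were not called as a list (adjusted p = 0.834 by the same test). TotE had 764 ± 253 against 849 ± 256, TotF 269 ± 205 against 236 ± 142, TotZ 172 ± 152 against 135 ± 97.3, TotC 92.2 ± 75.7 against 75.7 ± 103, and TotB 56.2 ± 31.5 against 37.9 ± 40.3, below the limit in both groups. JAK/STAT pathway genes (6 of 7 higher), DNA damage and cell death genes (11 of 14 higher, with Ku80 at 0.68 ± 0.36 and Irbp at 0.43 ± 0.33, log2 and SE), unfolded protein response genes (8 of 11 higher) and autophagy genes (6 of 14 higher) were not called, with adjusted p-values of 0.518, 0.182, 0.861 and 0.861 by camera with Benjamini-Hochberg adjustment. The DNA damage list passed without the dimmest 50% of probe sets (0.0327; adjusted p = 0.971 with an estimated correlation on all 6 arrays).

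Fbp1, which encodes a receptor for larval serum proteins, had the smallest unadjusted p among yolk and larval serum protein genes. Its signal was 439 ± 476 in DMSO (SD, n = 3), with 986 on DMSO 1, and 21.4 ± 0.121 in MeHg, where it was below the background limit on all 3 arrays, so that it was at least 1.82-fold lower. This bound was 1.02-fold without DMSO 1 and 2.74-fold without DMSO 3. It was the only member of any list to pass when adjusted over the list alone by limma (1 of 6 in its list, 0 with the block), and it did not pass over all genes (adjusted p = 1.00 by limma with Benjamini-Hochberg adjustment). Yp2, a yolk protein gene, was below the limit in both groups. The list had 5 of 6 members lower and was not called (adjusted p = 0.361 by camera with Benjamini-Hochberg adjustment), but passed without DMSO 2 (0.0425; adjusted p = 0.971 with an estimated correlation on all 6 arrays).

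Among the remaining lists, ecdysone genes were split 10 to 10, with the synthesis gene dib at 397 ± 220 against 132 ± 70.7 (SD, n = 3 each, log2 difference 1.45 ± 0.53 SE) and positive in 2 of 3 pairs. Maternal oogenesis transcripts were split 9 to 9, with the posterior determinant osk at 1.01 ± 0.45 and the translation regulator png at -1.12 ± 0.51 (log2, SE), each with the same direction in 3 of 3 pairs. The 9 to 9 split averaged over opposite pairs, with mean differences of -0.73, 0.33 and 0.24 in pairs 1, 2 and 3 and 14 of 18 genes higher in each of pairs 2 and 3. The list passed, higher in MeHg, without MeHg 1 (adjusted p = 0.0222) and without both replicate 1 arrays (0.0268, chosen after seeing the data), by camera with Benjamini-Hochberg adjustment. It had an adjusted p = 0.971 with an estimated correlation on all 6 arrays, and 0.878 with the block as well. The maternal list had a mean of -0.05 and a median of -0.02, while camera placed it higher. Mean and median also differed in sign for glia markers (0.05 and -0.02), axon guidance genes (0.05 and -0.00) and fat body genes (0.01 and -0.02). Neuroblast markers were higher at 12 of 16 and passed without MeHg 1 (adjusted p = 0.0119 by the same test; adjusted p = 0.971 with an estimated correlation on all 6 arrays, and 0.878 with the block as well), with ind at 1.57 ± 0.72 and SoxN at -0.25 ± 0.28. The segmentation gene ftz was above the background limit on 2 of the 3 MeHg arrays and on no DMSO array. Ribosomal proteins (20 of 29 higher), axon guidance genes (8 of 17), chorion and vitelline membrane genes (7 of 12), glia markers (5 of 13), fat body genes (7 of 16), hemocyte markers (7 of 19) and trachea and salivary gland markers (8 of 11) were not called, and adjusted p-values over these 10 lists, without segmentation genes, ran from 0.518 to 0.993 by camera with Benjamini-Hochberg adjustment. Hox genes (4 measured) and replication-independent histones (2 measured) were too few to test, with mean log2 differences of 0.03 and 0.22.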

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

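Counts over other splits of the arrays, and list tests leaving out an array or estimating the correlation without the block, were fixed beforehand. All other tests in this part were chosen after the result was seen. A control probe set, left out of the comparison, had a mean signal of 296 in MeHg and 142 in DMSO, with all 3 MeHg arrays above all 3 DMSO arrays and above the background limit. Of the 183 control probe sets, 16 had all MeHg arrays above all DMSO arrays and 4 the reverse, where chance puts 5% on each side. Among the 16, some rose from levels as low as those of the dim genes named as higher. Their means in DMSO and MeHg were, for example, 25.6 and 169, or 4.07 and 70.2. Groups of 3 arrays were not searched for outlying values.

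No probe set passed the threshold in the real split, higher (0) or lower (0), and the highest count of the other splits was also 0 in each direction, so that 10 of 10 splits gave as many. For gene lists, 6 of the 10 splits gave as many as the real 3, and the highest other count was 14. In the blocked fit, 2 of the 4 splits that part all numbered pairs gave as many probe sets with an unadjusted p under 0.05 as the real 945, and the highest other was 948. With 10 or 4 splits, a share under 0.05 is out of reach. The 4 splits that kept both replicate 1 arrays on 1 side gave 10 to 14 lists, which points to a structure of the samples.

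The replicate 1 arrays of both groups stood apart from the others. A uniform difference in scale would move spike-in controls and all lists alike. Muscle markers and Enhancer of split genes instead shifted in opposite directions, with a gap of 3.84 (log2) against a spike-in shift of 0.62. A labelling difference that varies between transcripts need not move lists alike, and these lists were picked after their shifts were seen. The test therefore cannot exclude a labelling difference. Whether the replicate 1 embryos were older stays open: 8 of 8 lists of early and late genes moved that way, but the lists were picked after their shifts were seen. Of other lists, those of trachea and salivary glands (-0.47), axon guidance (-0.43) and glia (-0.27) were lower there, and gut (0.02), fat body (0.13) and hemocyte (0.25) lists were higher. Larger shifts were seen in JAK/STAT (-0.85), proneural (-0.82), nucleolar (-0.80), Notch component (-0.77) and maternal (-0.69) genes, all lower. Turandot genes (1.28) and yolk and larval serum protein genes (0.82) were higher. The labels give no age, so no biological explanation was tested by the design, and other differences between collections stay open.

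A difference of the MeHg 2 array alone may account for the lower muscle, cuticle and neuron signal in MeHg, since the mean over the genes of these lists in pairs 1 and 3 was 0.0751 ± 0.04 (SE over genes). For the higher DNA replication genes, that mean was 0.267 ± 0.06, so their difference was not confined to pair 2. The list was not called without MeHg 2, however (adjusted p = 0.783 by camera with Benjamini-Hochberg adjustment). That fit gives replicate 1, where the list was lower in both groups (median -0.98), more weight in MeHg than in DMSO. The loss can come from this weight alone, so it does not show that the call rests on MeHg 2. An error over genes measures no spread between arrays, so whether the call rests on MeHg 2 stays open. After removing the shift of other genes at the same position on the axis separating replicate 1, 0.251 ± 0.05 of the mean difference was left, and the 3-prime to 5-prime ratio, the measure of RNA integrity, was higher in MeHg in 1 pair and lower in pairs 2 and 3. Genes of a list are not independent, so these errors are too small. The variation that coregulated genes share (p = 0.364 by limma's camera with an estimated correlation, p = 0.0581 with the block as well, and p = 0.0451 by fry with the block, unadjusted), the differing source labels and methylmercury itself all stay open. By fry with the block, the list had an adjusted p of 0.481 (Benjamini-Hochberg). The respiratory chain list and the trachea and salivary gland list had smaller unadjusted p-values by that test (0.0274 and 0.0330).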

How the results depend on the processing

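The alternatives that left out both replicate 1 arrays, or joined the replicate block to a variance trend or to an estimated correlation, were chosen after seeing the data. The counts of probe sets past the threshold were 0 higher and 0 lower under all alternatives run with limma and Benjamini-Hochberg adjustment, with 29 to 2634 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0548, with array weights.

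The count of lists, 3 in the reported test, was 10 with the replicate block, 8 without the dimmest 50% of probe sets, 6 without both replicate 1 arrays and 9 with block and variance trend. It was 0 with array weights, with an estimated correlation, with fry, and with block and estimated correlation, and ran from 0 to 10 when single arrays were left out (0 without DMSO 1, 8 without DMSO 2, 9 without DMSO 3, 10 without MeHg 1, 1 without MeHg 2 and 1 without MeHg 3). Adjusted p-values (camera or fry, Benjamini-Hochberg) for the DNA replication, proneural and gut lists were 0.971 each with an estimated correlation, 0.962 each with fry, 0.878 each with block and estimated correlation, and 0.103, 0.712 and 0.0736 with array weights. Without both replicate 1 arrays the proneural and gut lists had 0.447 and 0.892, while the DNA replication list still passed. The gut list had 0.0519 with a pseudocount of 1 and 0.0591 with block and variance trend. Leaving out single arrays gave 1.01e-05 to 0.822 for DNA replication, 0.00058 to 0.728 for proneural and 5.5e-06 to 0.698 for gut genes. Leaving out a single array also changes the weight of replicate 1 between the groups, which moves lists that differ between replicate numbers. The cause was otherwise not tested. The block changed no other call than those given beside the lists.

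For the 87 named genes, 1350 of 1406 values under the alternatives had the same sign, 56 in 22 genes changed sign, and 0 passed the threshold. Of the sign changes, 0 were in the 24 genes with the clearest differences. Their lack of overlap between groups largely fixes this, so it is no sign of robustness. Signal over background limits these genes, since 0 of the 24 were above the limit on all 6 arrays.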

Other observations

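The list test without MeHg 1, the estimated correlation without the block, and the naming of osk by the rule were fixed beforehand. All other genes and tests in this part were chosen after their values were seen. Several well-measured genes kept 1 direction in 3 of 3 pairs, although none passed the threshold. They were picked from all probe sets, many of which keep 1 direction by chance alone, so this is no support for a change. The peroxiredoxin gene Prx6a had 1434 ± 420.0 in MeHg against 2750 ± 367 in DMSO (SD, n = 3 each, log2 difference -0.96 ± 0.32 SE), while its relative Prx6c had 31619 ± 11512 against 18378 ± 8271 (0.83 ± 0.48). The gene mxc had 1854 ± 540.5 against 1022 ± 245 (0.83 ± 0.36), and Gnmt, a glycine N-methyltransferase gene, had 812 ± 272 against 411 ± 70.3 (0.92 ± 0.34).

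Some maternal transcripts were low on the MeHg 1 array. The anterior determinant bcd had a signal of 39.4 there, against 2033 on DMSO 1 and 3727 and 2617 on MeHg 2 and 3, swa had 46.0 against 572, and smg had 2614 against 9201. In pair 1, 14 of 18 genes of the maternal list were lower and 5 were lower by more than 1 on the log2 scale, while gcl, tud and mod differed by -0.14, 0.22 and -0.03, and osk and gnu were higher by 1.02 and 1.04. In pairs 2 and 3, 14 of the 18 were higher in MeHg in each, and the list passed the threshold without MeHg 1 (adjusted p = 0.0222, limma's camera with Benjamini-Hochberg adjustment). It had an adjusted p = 0.971 with an estimated correlation on all 6 arrays, and 0.878 with the block as well. Embryos at the segmentation stage in the DMSO collection would bring segmentation genes with them, but these were higher in MeHg 1 by a mean of 0.776 ± 0.21 (SE over genes). Loss of RNA or label on the MeHg 1 array could be neither shown nor excluded, with a median of -0.138 ± 0.19 over the list. The 3-prime to 5-prime ratios of 3 control transcripts were higher on MeHg 1 (3.15, 4.41 and 4.31) than on DMSO 1 (2.32, 3.46 and 3.28), and the highest of all 6 arrays. A first form of that test, which asked whether all egg transcripts moved together without allowing for the spread, was replaced after its value had been seen. Unfertilised eggs or cleavage-stage embryos were not tested.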
